A study of Mus musculus with 6 samples.

How the data were processed

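RNA was sequenced in 6 libraries labelled bEnd.3, 3 of control cells and 3 of cells given mitochondria. bEnd.3 is a mouse brain endothelial line immortalised with the polyomavirus middle T antigen. Per the labels' protocols, the mitochondria came from primary mouse astrocytes and were added in 100 µl of medium, control cultures received the same volume of medium alone, and cells were collected after 24 h. RNA was isolated on silica columns and made into strand-specific mRNA libraries, per the labels' protocols. The labels number the libraries 1 to 3 within each group. Nothing in them says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

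The authors deposited 1 column of values per library for 55335 mouse gene identifiers. The deposited values were read as FPKM, that is, fragments scaled by transcript length and library size. The headers name no unit, and the reading rests on the values. They were not whole numbers, and each library summed to between 281433 and 297838, too low for TPM. In genes with a single transcript, the value multiplied by the exonic length clustered at multiples of 1 constant per library. Per the submitters' processing notes, FastQC 0.11.5, STAR 2.5.3a and StringTie 1.3.1c were used with the mouse build GRCm38 (mm10). The notes give no roles, no settings and no annotation release, and whether strand was used in quantification is not given in the sources used here. Gene symbols and positions came from the GENCODE M21 annotation of GRCm38, and 55154 of the 55335 identifiers matched it. Coordinates are on GRCm38.

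Counts were not analysed here, so depth was estimated from the FPKM themselves. The constant worth of 1 fragment implied 17100000, 18500000 and 21200000 fragments in control replicates 1 to 3, and 27200000, 21900000 and 24000000 in mitochondria replicates 1 to 3. Between 29.6% and 32.5% of the low values lay within 0.02 of a whole multiple, so whole reads were not recovered and no count model was used. Between libraries, Pearson's correlation of log2 values across genes was 0.983 to 0.994, where genes are not independent replicates. Of the 11842 genes at 1 FPKM or more in all libraries, 0.00% had identical values in any 2 libraries, and 25970 identifiers were at 0 in every library.

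The comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group as the only term and an empirical Bayes variance with trend and robust options. Genes at 1 FPKM or more in at least 3 of the 6 libraries were tested, and p-values were two-sided with Benjamini-Hochberg adjustment over all genes tested. A gene was called changed at an adjusted p under 0.05. Log2 changes are mitochondria minus control on the log2(FPKM + 1) scale, which understates the change of low genes. Means are given in FPKM with the SD over 3 libraries. The same code was tested on simulated data with the real genes' means, with 200 genes changed in each of 20 simulations of 3 against 3 libraries over 12639 genes. It recovered 50.2% of the 1.5-fold changes and 77.0% of the 2-fold changes, and 4.3% of its calls were false. A simulated list of 25 genes shifted by 0.25 on the log2 scale was found in 20 of 20 simulations. The simulated noise was drawn independently for each gene, whereas correlations estimated within the real lists reached 0.72 (cell cycle). The simulations therefore do not show how the tests do with correlated genes.

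The 33 gene lists were tested with camera, limma's competitive set test, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 31 lists with at least 5 tested members. The other settings fixed in advance were camera with an estimated correlation and fry, limma's self-contained rotation test. Counts of called members are given over all genes tested and adjusted over the list alone. The summed FPKM of transcripts encoded by mitochondrial DNA and of astrocyte markers were compared by an exact two-sided permutation test, which cannot go below p = 0.1 with 3 against 3.

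The test, the groups, the gene lists and the rule for the genes named were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 FPKM and no overlap between the groups, leaving out genes with predicted names only. It added up to 4 called members of each list with the smallest p, or, where no member was called, the member with the smallest p as a value only. It also named Cldn5, Ocln, Tjp1, Cdh5, Plvap, Slc2a1, mt-Nd1, mt-Co1, Gfap and Aqp4 in any case. Not every gene that the rule took is named in the text. The other settings fixed with them were pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 FPKM, TMM scaling, quantile normalization, TPM, a plain empirical Bayes fit, omission of genes encoded by mitochondrial DNA, the replicate number as a block, and omission of each library in turn. Array weights, omission of overlapping genes and Fisher's exact test of called list members were chosen after seeing the data. Settings meant for counts were not run because the values are FPKM. For each named gene, the share of its 31-base words found in other annotated genes was computed from the reference transcripts, since such reads can be assigned to either gene.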

Results

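Gene expression was measured by strand-specific mRNA sequencing in 6 libraries labelled bEnd.3, of which 3 came from control cells given medium and 3 from cells given mitochondria isolated from primary mouse astrocytes. Cells were collected after 24 h. The FPKM implied depths of 17100000 to 21200000 fragments in the controls and 21900000 to 27200000 in the mitochondria libraries, so the mitochondria libraries were deeper without overlap. Of 55335 gene identifiers, 12639 were expressed highly enough to be tested. The series addresses how astrocytes act on the blood-brain barrier through mitochondrial transfer, and the single comparison in its design is cells with mitochondria against cells with medium alone.

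After 24 h with mitochondria, cells held lower levels of genes such as Crk, Fbln5 and Orai1 and higher levels of genes such as Sncg and Gpx3. Crk, an adaptor that links tyrosine kinases to downstream signalling, fell from 27.0 ± 1.17 to 9.53 ± 0.697 FPKM (SD, n = 3). Fbln5, which takes part in elastic fibre assembly, fell from 13.9 ± 0.688 to 5.34 ± 0.746 FPKM, and Orai1, the pore of the store-operated calcium channel, fell from 14.98 ± 0.187 to 6.88 ± 0.808 FPKM. Sncg, which encodes gamma-synuclein, rose from 3.11 ± 0.603 to 10.5 ± 0.225 FPKM, and Gpx3, a secreted glutathione peroxidase, rose from 72.3 ± 14.0 to 143 ± 14.0 FPKM (SD, n = 3 in each group). In all, 141 genes changed at an adjusted p under 0.05 by limma with Benjamini-Hochberg adjustment, 59 higher and 82 lower with mitochondria, and 133 of them were protein-coding. On the log2(FPKM + 1) scale, which understates the fold of low genes, 15 genes changed at least 2-fold, 5 higher and 10 lower. The median absolute log2 change of all called genes was 0.55, and the median was 0.53 for those higher and −0.58 for those lower. At an unadjusted p under 0.05 there were 1757 genes, where chance alone gives 632.

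Among the falls, Crk (ENSMUSG00000017776, chromosome 11, 75679259 to 75706908) changed by −1.41 on the log2 scale (SE 0.07, limma adjusted p = 0.00116). Golm1 (ENSMUSG00000021556, chromosome 13, 59634626 to 59675811), a Golgi membrane protein, fell from 22.1 ± 0.354 to 8.71 ± 0.484 FPKM, a log2 change of −1.25 (SE 0.06, limma adjusted p = 0.00116). Chmp3 (ENSMUSG00000053119, chromosome 6, 71543797 to 71582609), a subunit of the membrane-remodelling ESCRT-III complex, fell from 37.9 ± 3.06 to 17.2 ± 1.18 FPKM. Its log2 change was −1.10 (SE 0.08, limma adjusted p = 0.00547). Fbln5 (ENSMUSG00000021186, chromosome 12, 101746565 to 101819055) changed by −1.24 (SE 0.09), Prr9 (ENSMUSG00000056270, chromosome 3, 92122204 to 92123947) by −1.04 (SE 0.08) and Orai1 (ENSMUSG00000049686, chromosome 5, 123015074 to 123030456) by −1.03 (SE 0.08), each with a limma adjusted p of 0.00576. The largest log2 fall was that of Crabp1, a retinoic acid binding protein, which went from 9.05 ± 3.20 to 2.42 ± 0.511 FPKM, a change of −1.52 (SE 0.22, limma adjusted p = 0.0343). Mgp, an inhibitor of calcification, fell from 15.8 ± 3.88 to 6.56 ± 0.417 FPKM, and Mfap4, a microfibril-associated protein, from 3.67 ± 0.769 to 1.14 ± 0.173 FPKM. Fbn1, which encodes fibrillin-1, fell from 25.1 ± 5.04 to 12.5 ± 0.753 FPKM. Mmp3, a matrix metalloproteinase, fell from 216 ± 49.4 to 102 ± 8.86 FPKM, and 14.6% of its 31-base words also occur in other genes, chiefly Mmp10, so reads from those words can be assigned to either gene. Egr1, an immediate early transcription factor, fell from 23.3 ± 4.49 to 11.3 ± 1.52 FPKM. The adjusted p-values of these last 5 genes in limma lay between 0.0208 and 0.0461.

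Among the rises, Sncg (ENSMUSG00000023064, chromosome 14, 34370274 to 34374789) changed by 1.49 on the log2 scale (SE 0.11, limma adjusted p = 0.00547). Ncald (ENSMUSG00000051359, chromosome 15, 37366175 to 37792570), a neuronal calcium sensor, rose from 6.84 ± 0.671 to 14.8 ± 0.790 FPKM, a log2 change of 1.02 (SE 0.08, limma adjusted p = 0.00576). Usf3 (ENSMUSG00000068284, chromosome 16, 44173246 to 44227465), a basic helix-loop-helix protein, had the largest log2 rise among called genes, 1.67 (SE 0.20, limma adjusted p = 0.0220). It went from 0.862 ± 0.489 to 4.85 ± 0.885 FPKM. Akr1b7, an aldo-keto reductase, rose from 0.732 ± 0.369 to 3.20 ± 0.410 FPKM. The predicted gene Gm20537, with a mean under 1 FPKM and chosen for mention after its values were seen, completes the 5 rises of at least 2-fold on the log2(FPKM + 1) scale with a change of 1.23 (limma adjusted p = 0.0324). Gpx3 changed by 0.99 (SE 0.14, limma adjusted p = 0.0343). Bmp5, a bone morphogenetic protein, rose from 1.26 ± 0.187 to 3.35 ± 0.420 FPKM, and Tbx2, a T-box transcription factor, from 3.78 ± 0.366 to 7.27 ± 0.367 FPKM. Ddx4, a germ cell RNA helicase, rose from 2.83 ± 0.314 to 5.74 ± 0.295 FPKM, and Sulf1, which removes sulphate from heparan sulphate, from 4.55 ± 0.396 to 8.51 ± 0.102 FPKM. Serinc5 rose from 26.3 ± 2.52 to 43.5 ± 1.02 FPKM, Itih4 from 1.67 ± 0.0709 to 3.51 ± 0.704 FPKM, and Igf2r, the receptor that carries lysosomal enzymes, from 70.9 ± 5.09 to 112 ± 2.41 FPKM. The adjusted p-values of the genes from Bmp5 to Igf2r and of Akr1b7 lay between 0.00967 and 0.0418 in limma.

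**Figure D1:**
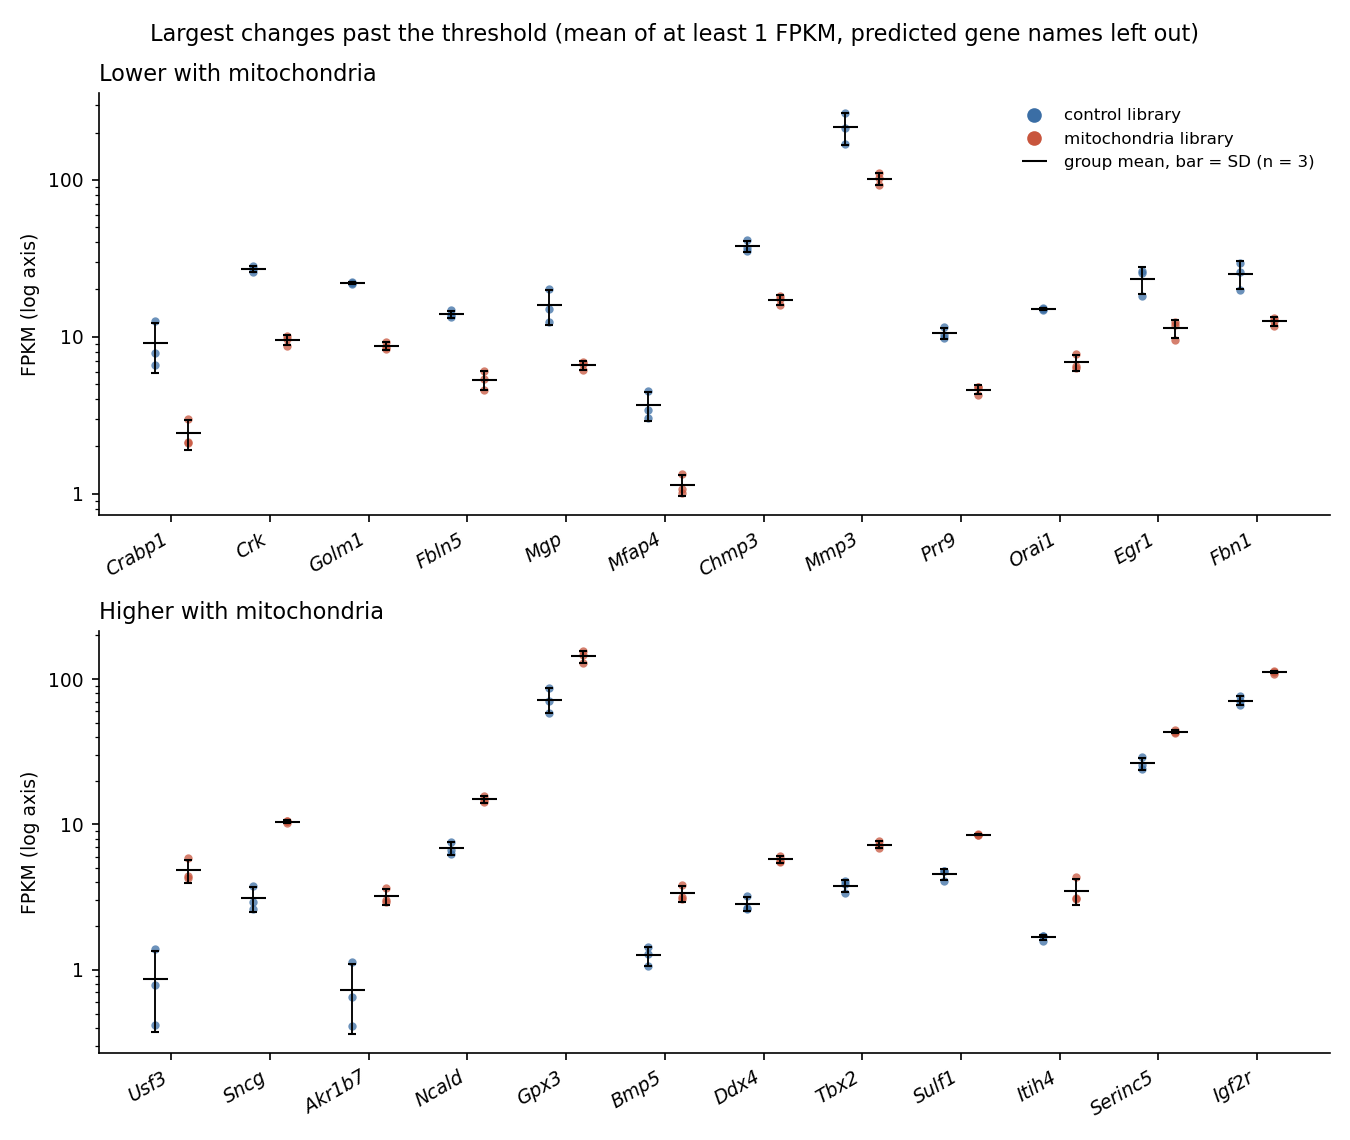
FPKM of each library, on a log axis, for the 12 largest falls and the 12 largest rises past the threshold among genes with a mean of at least 1 FPKM, predicted gene names left out; points are libraries and black bars the group mean with its SD (n = 3). The rule took only genes whose 3 mitochondria libraries lie on one side of the 3 control libraries, so this separation is not a result. Examples are the control and mitochondria means of Crk, 27.0 and 9.53 FPKM, and of Sncg, 3.11 and 10.5 FPKM.

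In all 141 called genes the mitochondria libraries and the control libraries did not overlap, a criterion that 2655 of the 12639 tested genes met (21.01%) and that chance gives for 10%. The number of calls depended on single libraries. It was 84, 22 and 88 without control replicates 1, 2 and 3, and 14, 16 and 28 without mitochondria replicates 1, 2 and 3. The genes Crk, Golm1, Fbln5, Chmp3, Prr9, Orai1, Col1a1, Sncg and Ncald passed the threshold in each of these 6 fits. The other called genes in the rule for names passed in 0 to 4 of them, with Gpx3 and Usf3 in 2, Crabp1, Mmp3, Fbn1 and Egr1 in 1 and Itih4 in 0.

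In the barrier lists of transporters, junctions and caveolae, 1 gene passed the threshold. The endothelial genes Cdh5, Pecam1 and Cldn5 averaged 0.03, 0.19 and 0.03 FPKM in these 6 libraries. Whether the cells are brain endothelium is therefore open, and these values may not describe the barrier. Of the 35 genes for transporters and receptors of the barrier, 22 were expressed and tested, and Mfsd2a, a lipid transporter, was the 1 that changed. It fell from 10.1 ± 0.368 to 6.77 ± 0.229 FPKM, a log2 change of −0.51 (SE 0.06, limma adjusted p = 0.0182), and passed in 2 of the 6 fits without a library. Adjusted over the list alone, 2 transporter genes were higher and 2 were lower. Slc2a1, the glucose transporter GLUT1, was at 30.02 ± 5.94 and 26.2 ± 4.10 FPKM (limma adjusted p = 0.669). None of the 18 tested genes of tight and adherens junctions passed the limma threshold, over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. The smallest p among them was that of Jam2, at 16.0 ± 1.84 and 11.7 ± 1.19 FPKM (limma adjusted p = 0.134). Ocln was at 10.98 ± 1.36 and 8.78 ± 1.55 FPKM, and Tjp1, which encodes ZO-1, at 13.9 ± 1.53 and 16.4 ± 0.418 FPKM, with limma adjusted p-values of 0.391 and 0.293. The junction list had a median log2 change of 0.03 and a mean of −0.03, and camera gave it an adjusted p of 0.575. Caveolae and transcytosis had 0 of 16 genes called in limma and 3 at an unadjusted p under 0.05, with Cavin1 at 262 ± 11.5 and 231 ± 3.70 FPKM (limma adjusted p = 0.208). Plvap, a marker of fenestrated endothelium, was low in both groups, at 1.91 ± 0.440 and 1.70 ± 0.254 FPKM (limma adjusted p = 0.787).

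Endothelial identity genes were expressed unevenly in all 6 libraries, in both groups. Cdh5, which encodes VE-cadherin, lay between 0.01 and 0.07 FPKM, Pecam1 between 0.13 and 0.27 FPKM and Cldn5, the main claudin of brain endothelium, at 0.13 FPKM or less. In contrast Eng reached 61.1 FPKM on average, Cd34 70.2 FPKM, Flt1 8.89 FPKM and Tie1 5.61 FPKM. Of the 35 endothelial identity genes, 14 were under 1 FPKM in every library and 19 were tested. Cd34, a surface sialomucin of endothelial and progenitor cells, was the 1 identity gene called, and it rose from 60.3 ± 2.49 to 80.1 ± 1.84 FPKM, a log2 change of 0.41 (SE 0.05, limma adjusted p = 0.0265), and passed in 1 of the 6 fits without a library. Adjusted over the list alone, 1 identity gene was higher and 2 were lower. The list as a whole had a camera adjusted p of 0.575, with a median near 0.00 and a mean log2 change of −0.06. Pecam1, Eng, Flt1 and Tie1 were chosen for mention after their values were seen. The angiogenesis list had Angpt1, a ligand of the Tek receptor, as its 1 called gene of 17, and it fell from 16.7 ± 1.70 to 11.5 ± 0.454 FPKM, while 6 of its genes were lower adjusted over the list alone. The call of Angpt1 was kept in 1 of the 6 fits without a library and lost with no filter, quantile normalization, TPM, plain empirical Bayes, omission of mitochondrial DNA genes and the replicate block. The list's median was 0.00, its mean log2 change −0.08 and its camera adjusted p 0.141. Targets of Wnt (14 tested, Ccnd1 at 33.9 ± 0.490 and 38.2 ± 0.524 FPKM) and of Notch (9 tested, Hes1 at 13.003 ± 1.52 and 9.94 ± 1.00 FPKM) had 0 genes called in limma, 4 and 1 at an unadjusted p under 0.05, and camera adjusted p-values of 0.917 and 0.974. The Notch list had a median of 0.01 and a mean of −0.01 on the log2 scale.

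**Figure D2:**
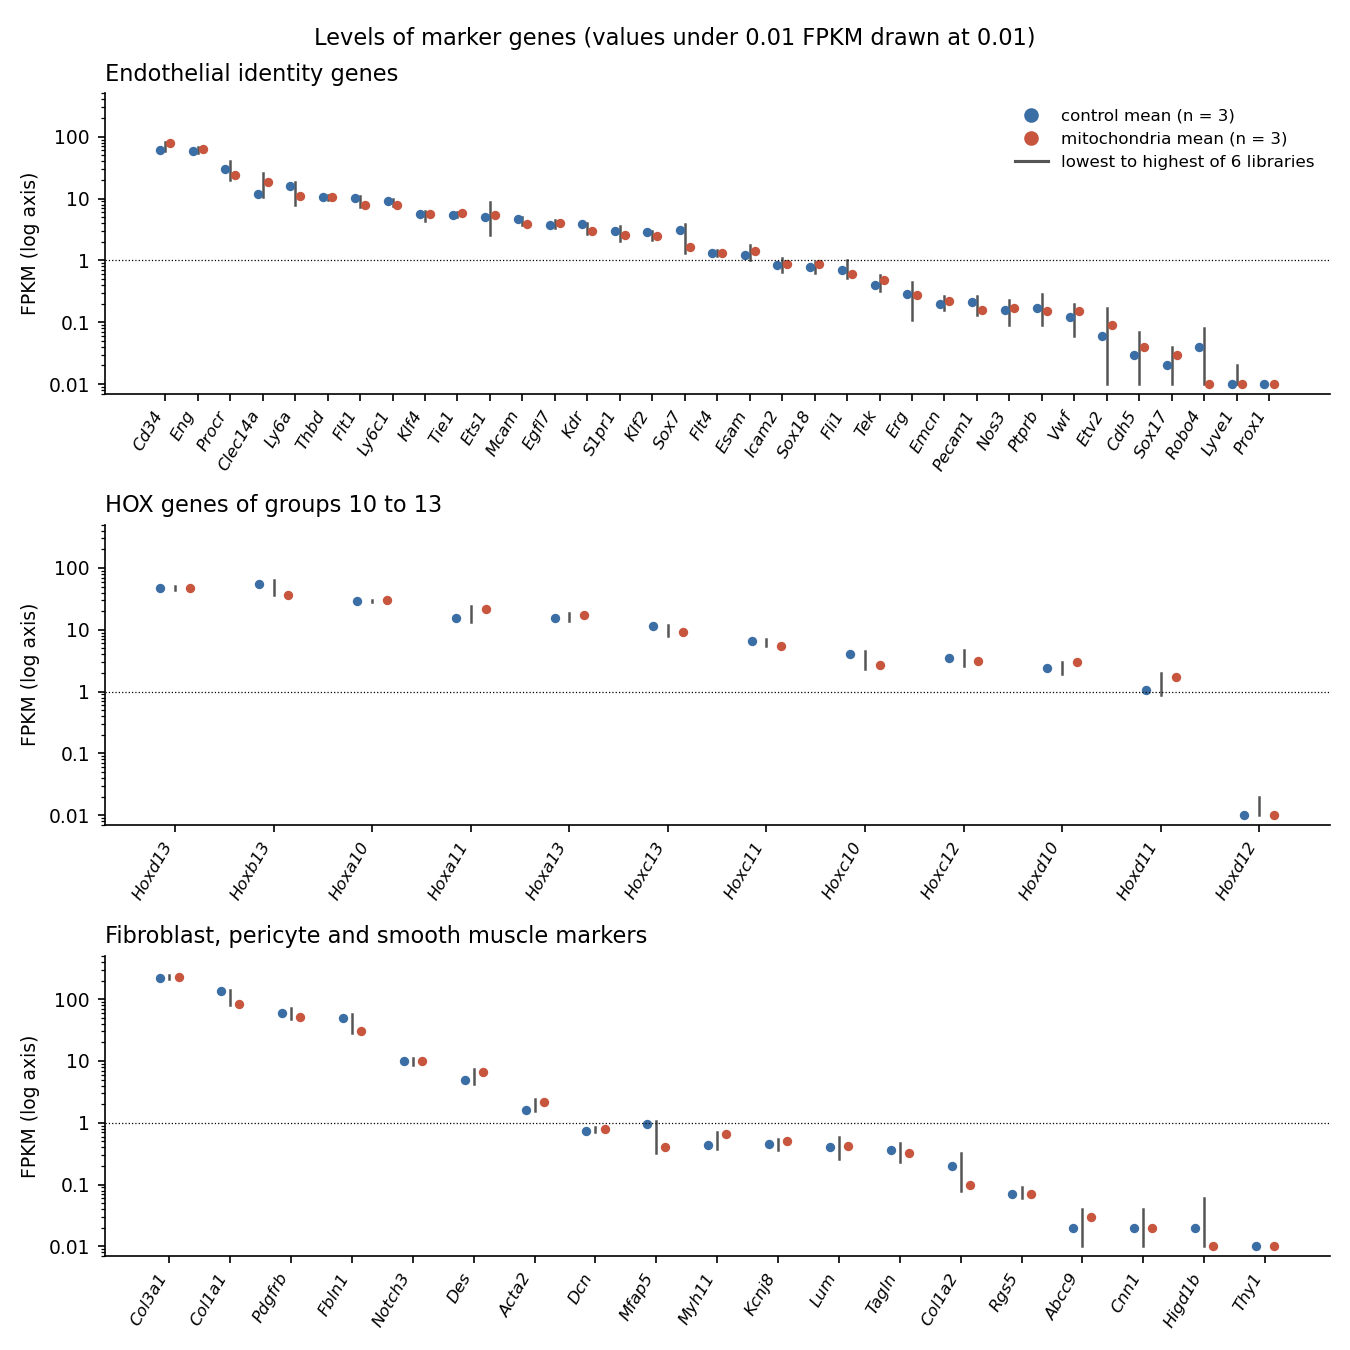
Levels of endothelial identity genes, of HOX genes of paralog groups 10 to 13 and of fibroblast, pericyte and smooth muscle markers, in FPKM on a log axis; points are group means (n = 3), lines run from the lowest to the highest of the 6 libraries, and the dotted line marks 1 FPKM. Cd34 and Eng lie above 50 FPKM, whereas Pecam1 and Cdh5 lie under 1 FPKM in both groups.

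Of the 33 gene lists, 31 had at least 5 tested members, and 11 of these passed camera with the preset correlation, 4 higher and 7 lower with mitochondria. None of the 11 passed with an estimated correlation, where 2 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.375. By fry, 2 lists, glycolysis and the fibroblast, pericyte and smooth muscle markers, moved one way on balance and 20 held genes that changed in either direction. Another division of the same 6 libraries into 3 and 3 gave 10 list calls.

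Immediate early genes, which respond within minutes to growth factors and stress, were lower as a list with mitochondria. Of 22 tested members 5 fell, Fos, Ier3, Dusp6, Fosl1 and Egr1, and adjusted over the list alone 11 were lower and 1 was higher. Fos fell from 3.38 ± 0.169 to 2.09 ± 0.156 FPKM, Ier3 from 82.8 ± 6.33 to 57.2 ± 3.50 FPKM, Dusp6 from 48.9 ± 1.68 to 38.9 ± 0.942 FPKM and Fosl1 from 7.92 ± 0.0943 to 5.48 ± 0.533 FPKM. In the 6 fits without a library limma called Egr1 in 1 and Fos, Ier3, Dusp6 and Fosl1 in 0, with adjusted p-values of these 4 from 0.0537 to 0.197. Dusp6 was called in 5 of 18 other settings and lost its call also with no filter, TMM, quantile normalization, TPM, plain empirical Bayes, omission of mitochondrial DNA genes and the replicate block. The list had a median log2 change of −0.23 and a camera adjusted p of 2.56e-06, with an adjusted p of 0.663 under an estimated correlation. Fisher's exact test of its called members, chosen after seeing the data, gave an adjusted p of 0.000113.

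The list of TGF-beta targets and matrix genes was also lower. Of 31 tested members 4 fell and none rose in limma, and 9 were lower adjusted over the list alone. Ccn2, connective tissue growth factor, fell from 9.16 ± 0.667 to 4.94 ± 0.690 FPKM. The matrix genes Sparc and Lama4 fell from 311 ± 12.4 to 234 ± 1.91 FPKM and from 15.1 ± 0.627 to 10.4 ± 0.855 FPKM. In the 6 fits without a library limma called Sparc in 1 and Ccn2 and Lama4 in 0, with adjusted p-values of the last 2 from 0.0534 to 0.153. The list's median log2 change was −0.13, with a camera adjusted p of 0.000226, an adjusted p of 0.761 with an estimated correlation, and an adjusted p of 0.00574 in Fisher's exact test of called members. Among 19 fibroblast, pericyte and smooth muscle markers 7 were tested and 2 fell. Col1a1, the alpha-1 chain of type I collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), fell from 138 ± 2.45 to 83.9 ± 3.19 FPKM, a log2 change of −0.71 (SE 0.05, limma adjusted p = 0.00547). Fbln1, a matrix fibulin, fell from 50.3 ± 7.75 to 30.5 ± 1.85 FPKM and passed in 1 of the 6 fits without a library. Adjusted over that list alone, 2 were higher and 2 were lower. Its camera adjusted p was 0.503, while fry gave an adjusted p of 0.0470 in the lower direction and Fisher's exact test of called members an adjusted p of 0.0258.

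The lists of the integrated stress and unfolded protein responses and of NRF2 targets were lower as well by camera with the preset correlation. Of 30 tested genes of the integrated stress and unfolded protein responses, Asns, the asparagine synthetase, passed over all genes. It fell from 15.6 ± 1.42 to 9.21 ± 0.128 FPKM, a log2 change of −0.70 (SE 0.07, limma adjusted p = 0.0148), and adjusted over the list alone 10 were lower and 1 was higher. Asns passed in 3 of the 6 fits without a library. The camera adjusted p was 0.00142, and the adjusted p was 0.761 with an estimated correlation. Of 25 tested NRF2 targets, Gsta4, a glutathione transferase, fell from 35.5 ± 3.31 to 24.9 ± 0.922 FPKM, and Gclc, which catalyses the first step of glutathione synthesis, from 25.5 ± 0.763 to 20.6 ± 0.257 FPKM. In the 6 fits without a library limma called Gsta4 in 1 and Gclc in 0 (adjusted p 0.0597 to 0.210), and Gclc lost its call also with no filter, TMM, quantile normalization, TPM, plain empirical Bayes, omission of mitochondrial DNA genes and the replicate block. Adjusted over the NRF2 list alone, 6 were lower and 1 was higher, with a camera adjusted p of 0.0302 and an adjusted p of 0.761 with an estimated correlation. Without control replicate 1, control replicate 2, mitochondria replicate 1 or mitochondria replicate 2 the NRF2 list did not pass camera, with adjusted p-values up to 0.322.

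Among metabolic lists, glycolysis was higher with mitochondria. Pfkl, the liver-type phosphofructokinase, was the 1 gene of 22 called, and it rose from 28.8 ± 0.792 to 36.7 ± 1.51 FPKM (log2 change 0.34, SE 0.05, limma adjusted p = 0.0420). Of the 22 genes 18 had positive log2 changes and 4 were higher adjusted over the list alone. The glycolysis list had a median log2 change of 0.18 and a camera adjusted p of 1.04e-05, and the adjusted p with an estimated correlation was 0.375. Its fry p was 0.00287 before adjustment and 0.0470 after it. Pfkl was called in 0 of the 6 fits without a library (limma adjusted p 0.0654 to 0.197). The list of fatty acid oxidation and PPAR targets had 1 of 26 genes called, Angptl4, a secreted lipase inhibitor and PPAR target that is not an enzyme of oxidation. It fell from 45.2 ± 2.43 to 33.9 ± 1.35 FPKM, with 0 calls in the 6 fits without a library (limma adjusted p 0.0650 to 0.174), and 3 genes were lower adjusted over the list alone, with a camera adjusted p of 0.0407 and an adjusted p of 0.793 with an estimated correlation. Cholesterol and lipid synthesis had 0 of 31 genes called in limma and 8 at an unadjusted p under 0.05, with Tm7sf2 at 7.70 ± 1.09 and 5.37 ± 0.132 FPKM, a camera adjusted p of 0.0387 in the lower direction and an adjusted p of 0.761 with an estimated correlation. The TCA cycle (19 tested, Pdhb at 23.0 ± 0.796 and 20.7 ± 0.629 FPKM) and hypoxia targets (22 tested, Ldha at 98.1 ± 7.95 and 120 ± 4.92 FPKM) had 0 genes called in limma, 1 and 7 at an unadjusted p under 0.05, and camera adjusted p-values of 0.575 and 0.396. The fatty acid and cholesterol calls were each lost in 4 of the 6 fits without a library, with adjusted p-values up to 0.343 and 0.190.

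The treatment itself delivers mitochondria, so transcripts of mitochondrial DNA were summed per library. The 3 control libraries held 30374 ± 765 FPKM and the 3 mitochondria libraries 32039 ± 1640 FPKM (SD, n = 3, exact two-sided permutation p = 0.3, where 0.1 is the smallest possible). This test did not pair libraries by number. Controls 1 to 3 held 30469, 31087 and 29566 FPKM and mitochondria replicates 1 to 3 held 33338, 32583 and 30196 FPKM. Each mitochondria library was thus above the control of its number, and replicate 3 was lowest in both groups. The difference of 1665 FPKM was 1015 without mitochondria replicate 1 (exact permutation p = 0.5) and 2586 without mitochondria replicate 3 (exact permutation p = 0.1). As a share of all FPKM this was 10.5% ± 0.288 and 11.1% ± 0.479 (exact permutation p = 0.2). None of the 15 genes was called in limma, and 0 had an unadjusted p under 0.05. mt-Nd1 was at 2807 ± 59.6 and 2960 ± 119 FPKM (limma adjusted p = 0.626), mt-Nd2 at 1587 ± 52.5 and 1737 ± 65.6 FPKM (limma adjusted p = 0.394), and mt-Co1 at 6844 ± 79.9 and 7207 ± 229 FPKM (limma adjusted p = 0.623). The list as a whole passed camera in the higher direction with an adjusted p of 0.0407, and its adjusted p was 0.793 with an estimated correlation. It did not pass with quantile normalization, with no filter, with the replicate block, or without control replicate 3, mitochondria replicate 1 or mitochondria replicate 2 (adjusted p up to 0.340 without 1 library). Several of these values are uncertain, since 63.9% of the 31-base words of mt-Co1 and 98.1% to 100% of those of mt-Nd3, mt-Nd4l, mt-Co2, mt-Co3 and mt-Atp6 also occur in other genes, mostly nuclear copies. For mt-Nd1 the share was 0.0%.

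The fixed lists of nuclear genes for OXPHOS, mitochondrial upkeep and mitochondrial ribosomes gave no calls in limma. Of 75 tested OXPHOS subunits 0 were called in limma, 5 had an unadjusted p under 0.05, 40 had positive and 35 negative changes, and Atp5g1, the one with the smallest p, was at 17.6 ± 1.36 and 15.1 ± 0.122 FPKM (limma adjusted p = 0.227). Mitochondrial biogenesis and dynamics (23 tested, Polg at 4.36 ± 0.253 and 3.82 ± 0.214 FPKM), the mitochondrial protein folding response (14 tested, Atf5 at 14.7 ± 0.528 and 11.7 ± 1.15 FPKM) and mitophagy and lysosome genes (26 tested, Tax1bp1 at 62.6 ± 1.56 and 52.4 ± 1.01 FPKM) had 0 genes called in limma, with 0, 2 and 7 at an unadjusted p under 0.05. Their camera adjusted p-values were 0.575, 0.503 and 0.813, and 4 mitophagy and lysosome genes were lower adjusted over the list alone. The mitophagy median was 0.01 on the log2 scale while camera's direction was lower. Mitochondrial ribosomal proteins (78 tested, 0 called in limma, 7 at an unadjusted p under 0.05) had a camera adjusted p of 0.211. Mrpl53 was at 15.9 ± 0.649 and 13.2 ± 0.0771 FPKM but shares 84.4% of its 31-base words with an overlapping gene model. Cytosolic ribosomal proteins were higher, with 73 of 83 positive, a median log2 change of 0.13 and a camera adjusted p of 1.29e-10, against an adjusted p of 0.761 with an estimated correlation. None of the 83 was called in limma, 18 had an unadjusted p under 0.05, and Rps12 was at 57.9 ± 4.11 and 75.7 ± 4.07 FPKM, with 29.8% of its 31-base words in other genes.

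Inflammatory and growth lists gave few calls. In the list of NF-kB targets and leukocyte adhesion, Cxcl1, a neutrophil-attracting chemokine, was the 1 gene of 22 called and fell from 59.8 ± 5.21 to 36.4 ± 1.34 FPKM, a log2 change of −0.70 (SE 0.07, limma adjusted p = 0.0148), and passed in 2 of the 6 fits without a library. Adjusted over that list alone 1 was higher and 2 were lower, and its camera adjusted p was 0.676. Interferon response genes were higher as a list, with 29 of 40 positive and a median log2 change of 0.18. Their camera adjusted p was 0.00200, the adjusted p with an estimated correlation was 0.793, and 0 of 40 were called in limma against 5 at an unadjusted p under 0.05, with Ifit2 at 14.4 ± 0.919 and 18.2 ± 0.137 FPKM (limma adjusted p = 0.0665). The interferon list did not pass without control replicate 3 or mitochondria replicate 3, with adjusted p-values up to 0.242. Cell cycle genes (40 tested, Ccnd1 having the smallest p) and p53 targets (25 tested, Btg2 at 16.8 ± 1.03 and 13.2 ± 0.579 FPKM) had 0 genes called in limma, 1 and 8 at an unadjusted p under 0.05, and camera adjusted p-values of 0.0875 and 0.0840. Adjusted over the list alone 1 p53 target was higher and 3 were lower. Noncoding and histone RNAs, a check on the RNA fraction sequenced, were lower in 16 of 18 cases, with a camera adjusted p of 0.0302 and an adjusted p of 0.761 with an estimated correlation. Without control replicate 1, control replicate 2 or mitochondria replicate 3 this list did not pass (adjusted p up to 0.136). None was called in limma, 5 had an unadjusted p under 0.05, and Rn7s1, at 1.96 ± 0.588 and 0.903 ± 0.287 FPKM, shares 100.0% of its 31-base words with Rn7s2.

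**Figure D3:**
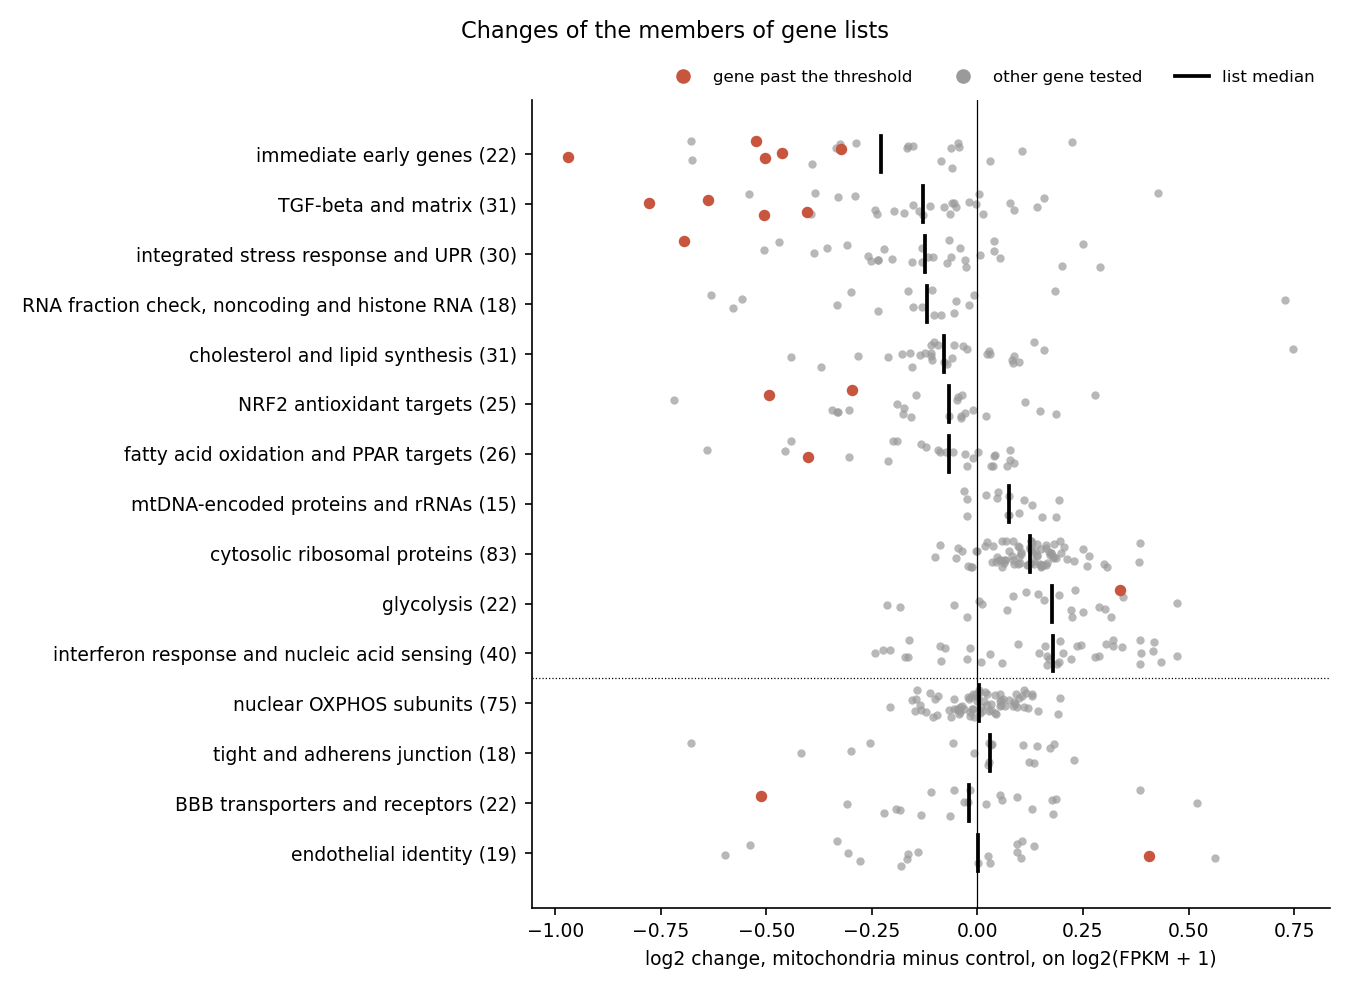
Log2 change of each tested member, mitochondria minus control on log2(FPKM + 1), for the 11 lists that passed camera with the preset correlation (above the dotted line) and 4 further lists (below it), with the number of members tested in brackets. Red points are genes past the threshold, grey points other tested genes and black bars list medians, which run from −0.23 for immediate early genes to 0.18 for the interferon response.

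Of the 30 markers of astrocytes, the cells that the mitochondria came from, 14 lay under 1 FPKM in every library and 9 had a mean of at least 5 FPKM, with Vim at 192 and Clu at 53.3 FPKM, both chosen for mention after their values were seen. Aqp4 was listed at 0 in all 6 libraries, and Gfap lay between 0.02 and 0.20 FPKM. Of these markers 14 were tested, 0 were called in limma and 4 had an unadjusted p under 0.05, with 1 higher and 1 lower adjusted over the list alone and a camera adjusted p of 0.238. Cpe, the one with the smallest p, was at 17.7 ± 2.26 and 26.2 ± 1.21 FPKM (limma adjusted p = 0.0527). The summed FPKM of astrocyte markers was 425 ± 19.2 in the controls and 437 ± 6.56 with mitochondria (SD, n = 3, exact two-sided permutation p = 0.5), and the difference of 11.8 FPKM was 0.849 without control replicate 2 and 18.8 without control replicate 1. Without 8 markers that endothelial cells also express the sum was 72.3 ± 6.68 and 93.4 ± 8.45 FPKM, with the 3 mitochondria libraries above the 3 controls (exact permutation p = 0.1, the smallest possible). Of this sum the controls already held Cpe at 17.7, Ndrg2 at 19.6 and Aldoc at 14.1 FPKM, against 26.2, 25.1 and 17.9 FPKM with mitochondria. Gfap, Aqp4, Sox9, Gjb6 and Slc1a3 stayed at 0.20 FPKM or less in every library, while Aldh1l1 rose from 0.39 to 1.06 FPKM. The sum therefore does not single out astrocyte RNA. Microglia and macrophage markers had 6 tested genes, 0 calls in limma and 2 genes at an unadjusted p under 0.05, with Trem2 at 1.03 ± 0.101 and 1.63 ± 0.145 FPKM and a camera adjusted p of 0.888, and adjusted over the list alone 1 was higher and 1 lower. Oligodendrocyte and neuron markers had 2 and 1 tested genes, too few for camera. Adjusted over the list alone 1 gene was higher in each, although lists this short are hardly adjusted. Pdgfra was at 18.4 ± 0.756 and 22.6 ± 0.587 FPKM and Tubb3 at 0.888 ± 0.363 and 1.44 ± 0.190 FPKM, with limma adjusted p-values of 0.0702 and 0.311.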

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

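Array weights, omission of overlapping genes, Fisher's exact test of called list members, set tests with array weights or without genes of mitochondrial DNA, and the share in percent were tests chosen only after the results were seen. The count of 141 called genes stayed within 1.5 times in 9 of 18 settings, and all of the 141 genes that a setting tested kept their direction in each. The groups of all 141 do not overlap, so settings that do not rescale the libraries, such as leaving out 1 library, could not reverse a direction. The count was 13 with no filter, where 29365 genes were tested. With array weights it was 1083, but these rest on the same 6 libraries and gave control replicate 2 a weight of 3.33. Leaving out 1 library gave 14 to 88 genes: 84, 22 and 88 without control replicates 1 to 3, and 14, 16 and 28 without mitochondria replicates 1 to 3. Besides fewer samples, the cause was not tested. The 15 genes of at least 2-fold on log2(FPKM + 1) became 25 and 32 with pseudocounts of 0.1 and 0.01, which enlarge the folds of low genes, 8 with no filter, 24 with TPM, 26 with array weights and 7 to 18 without 1 library (9, 9 and 7 without control replicate 2 and mitochondria replicates 1 and 2).

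Nothing in the labels says what libraries of the same number share. The correlations of deviations of same-numbered libraries across genes were 0.10, 0.05 and 0.30, and 3 of 6 libraries correlated best with their own number. Libraries of different number correlated at −0.20 to 0.12, so the replicate 3 libraries were the most alike, and a shared factor there stays open. With the replicate number as a block 56 genes passed, of which 43 were among the 141.

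In place of 11 lists, 0 passed with an estimated correlation, where 2 had an unadjusted p under 0.05. By fry 2 passed, of which glycolysis is among the 11, and by Fisher's exact test of called members 3 passed, of which immediate early genes and TGF-beta and matrix are among the 11. Leaving out 1 library gave 7 to 12 lists, 7 without control replicate 2 and 7 without mitochondria replicate 3. The calls of glycolysis, the stress response list, TGF-beta and matrix, immediate early genes and cytosolic ribosomal proteins held in all 6 of these fits. Those of mitochondrial DNA, fatty acid oxidation, NRF2, interferon, cholesterol and the RNA fraction were lost in 2 to 4 of them, and the cause was not tested. The 763 values under other settings of the 43 called genes taken by the rule for names all kept their direction and 527 passed the threshold. As the groups of these genes do not overlap, their direction was fixed in every setting that does not rescale the libraries. Plvap, not called, ranged from −0.17 to 0.0226 in log2 without 1 library, changing sign without control replicate 3. The sums of transcripts of mitochondrial DNA and of astrocyte markers kept their direction in 8 of 8 settings each, and neither can pass 0.05. Their differences moved by over 1.5 times without single libraries, as given beside them. Settings for counts (DESeq2, edgeR and voom variants) were not run because the values are FPKM. In the simulations, with independent noise for each gene, 1.5-fold changes were found in 50.2% of cases.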

Other observations

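The tests of the endothelial genes, of astrocyte RNA and of copy number below were chosen only after the results were seen. The genes named in this paragraph were chosen after their values were seen. How often each passed in the 6 fits without a library is not given here, and those fits called 14 to 88 genes in place of 141. Ltbp1, which anchors latent TGF-beta in the matrix, fell from 18.0 ± 0.894 to 9.57 ± 1.05 FPKM (SD, n = 3, limma adjusted p = 0.0141). F3, which encodes tissue factor, fell from 10.2 ± 0.308 to 5.69 ± 0.230 FPKM (limma adjusted p = 0.00576), and Has2, a hyaluronan synthase, from 10.6 ± 1.196 to 6.46 ± 0.251 FPKM (limma adjusted p = 0.0300). Spry4 and Errfi1, feedback inhibitors of receptor tyrosine kinase signalling, fell from 18.4 ± 0.641 to 14.2 ± 0.487 FPKM and from 91.0 ± 0.337 to 72.3 ± 2.13 FPKM (limma adjusted p = 0.0423 and 0.0324). Gsto1, a glutathione transferase, fell from 127 ± 2.04 to 72.4 ± 5.65 FPKM (limma adjusted p = 0.00703). Anxa2, a calcium-dependent membrane-binding protein, rose from 242 ± 8.47 to 314 ± 6.27 FPKM (limma adjusted p = 0.0324), and Selenop, the plasma selenium carrier, from 168 ± 11.7 to 222 ± 5.23 FPKM (limma adjusted p = 0.0458). The semaphorin receptors Plxnd1 and Plxna2 rose from 13.1 ± 1.13 to 19.5 ± 0.829 FPKM and from 3.34 ± 0.291 to 5.72 ± 0.203 FPKM (limma adjusted p = 0.0302 and 0.0190).

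In all 6 libraries labelled bEnd.3, 14 of 35 endothelial identity genes lay under 1 FPKM, among them Cdh5, Pecam1, Tek, Erg, Vwf and Sox17, while 7 HOX genes of paralog groups 10 to 13, which mark posterior and distal parts of the body, reached 5 FPKM or more, with Hoxd13 at 48.0 and Hoxb13 at 46.3 FPKM on average. A general failure to quantify genes is argued against. Of 254 genes that every cell uses, 0.4% lay under 0.5 FPKM, against 37.1% of the endothelial list. These 254 genes cannot show whether particular endothelial genes were missed. Low depth is also argued against, since 1 FPKM of the shortest endothelial gene under 1 FPKM would give 17.9 fragments in the shallowest library. Cells other than brain endothelium under the label are a candidate explanation that the 7 HOX genes go with, but which cells stays open: of 19 fibroblast, pericyte and smooth muscle markers 6 had a mean of at least 5 FPKM, with Col3a1 at 225 and Pdgfrb at 55.8 FPKM, and 11, among them Dcn, Lum and Thy1, lay under 1 FPKM in every library, while Eng and Cd34 were high. Of the transcription factors read after these results were seen, Twist1 had a mean of 66.1, Foxf2 30.7, Gata4 27.0, Prrx1 19.8 and Foxf1 15.1 FPKM. What these levels say about the cell type was not tested. A loss of endothelial expression during culture was not tested and stays open for the 14 low genes, but by itself it would not account for the 7 HOX genes. The 14 genes were under 1 FPKM in every library of both groups, whereas Cd34 was called higher and Hoxb13 lower with mitochondria (55.6 ± 7.31 and 37.1 ± 1.07 FPKM, limma adjusted p = 0.0487), and no biological explanation was tested.

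The real split of the 6 libraries gave 141 called genes, 15 of at least 2-fold on log2(FPKM + 1) and 11 lists, against 6, 4 and 10 in the highest other split, and in each case 1 of the 10 splits, the real one, gave as many, where 10 splits are too few for a share under 0.05. Greater depth of the mitochondria libraries is argued against as the whole cause: of the 141 genes with the smallest p in a fit of the other 4 libraries, 77 of them among the called genes, 84.4% kept their direction between control replicate 3 and mitochondria replicate 2, which have nearly equal depth, against 52.8% of all tested genes, with a median signed log2 change of 0.423 in this pair and 0.731 in the 4 libraries that picked them. Astrocyte RNA carried over is argued against for the 59 genes called higher, which rose by a median of 3.48 FPKM. The 15 astrocyte markers under 1 FPKM in every control rose by a median of 0 FPKM (95% bootstrap interval 0 to 0.0506, largest rise 0.671 FPKM for Aldh1l1). Against this, the sum of markers without those that endothelial cells also express was 72.3 FPKM in controls and 93.4 FPKM with mitochondria. That sum includes genes that the control cells already expressed, such as Cpe, Ndrg2 and Aldoc. Overlapping gene models are argued against by an odds ratio of 0.51 (95% interval 0.30 to 0.84, Fisher's exact p = 0.00481) for called genes to overlap another expressed gene. A response of the cells to mitochondria stays open as a hypothesis, as does a difference between the cultures or their handling, neither of which was tested.

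Of the 141 genes, 31 lay within 1 Mb of another called gene that changed in the same direction, against a median of 16 (95% range 6 to 26) in 10000 random sets of tested genes. Among them are Igf2r, the antisense transcript Airn and Gm16574 on chromosome 17, all higher with log2 changes of 0.65, 0.59 and 0.48, and Gsta4 with Gclc on chromosome 9, both lower with −0.49 and −0.30. Chromosome segments of different copy number that would shift the genes between as much as the pair itself are argued against for 14 of 17 pairs as a set. The tested genes between them, called ones included and counted once for each pair, came to 78, with 23 between Tbkbp1 and Hoxb13 and 11 between Serpinf1 and Crk. Their median signed log2 change was 0.065 (95% bootstrap interval, drawn by pair, 0.008 to 0.154) against a median absolute change of 0.503 for the 31. The 31 were picked by passing the threshold, which raises their median. The interval lies above 0, in the direction of the pairs, so a smaller copy number change stays open. Single pairs were not tested. Such segments stay open for the 3 pairs with no tested gene between, such as Cd34 with Plxna2. Reads assigned to both of a pair of overlapping models are argued against as the whole account, since 2 of 17 neighbour pairs overlap, Igf2r with Airn and Airn with Gm16574. Reads shared through similar sequence rather than overlap were not checked for every pair, for example Slfn5 with Slfn10-ps (log2 changes 0.62 and 0.57), and stay open. Shared regulation of neighbouring genes, with or without the treatment, also stays open and was not tested.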
